A study of Glycyrrhiza uralensis with 15 samples.

How the data were processed

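The samples were 15 libraries of whole Glycyrrhiza uralensis seedlings at 45 days, 3 in each of 5 groups. Per the labels' protocols, 60 seeds were sown in each pot of 1900 g of sterilized sand, 1 µg of total RNA was reverse transcribed, the cDNA was amplified by 14 cycles of PCR, and libraries were read on an Oxford Nanopore instrument. The labels also carry a sentence naming Illumina preparation, which was not used here. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Groups and replicate numbers came from the sample titles. The labels do not say that replicates came from separate pots, so p-values measure the spread between these samples, which may be technical.

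The authors deposited a table of CPM values per gene (30197 genes, of which 27475 carry IDs of the form used by a reference and 2722 carry IDs beginning with ONT) and a table of CPM values per isoform (53338 isoforms), per the file headers with a column for each library. Per the submitters' processing notes, minimap2 was used. Its version, the counting tool, the genome build, the filters and the treatment of reads that match near-identical genes are not given in the sources used here, so reads may be split between close copies of a gene. Each deposited CPM column summed to the same fixed total, and 100% of values were whole multiples of the worth of 1 read within a tolerance of 0.01. Whole reads were recovered in this way, 50341895 in all and 3039422 to 4043823 per library. Both tables gave the same totals. The files hold IDs with no gene names, and no reference table was used here, so the 25 gene lists and the organ markers fixed before the data were examined could not be run, genes are given by ID, and no coordinates are given.

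Values were analysed as log2(CPM + 1) in R 4.3.3. Genes or isoforms with a CPM of 1 or more (4 to 5 reads) in at least 3 libraries were tested, which left 22654 genes and 35504 isoforms. limma 3.58.1 was fitted to all 15 libraries with the group as the only factor and an intensity trend, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. A log2 difference is on the log2(CPM + 1) scale and understates the change of low genes, while fold values are ratios of mean CPM. The 7 comparisons and the F-test over 5 groups were fixed before the data were examined, and the 3 comparisons of treated droughted plants with CK were added afterwards. Isoform use was tested with diffSplice in limma, with loci taken from the isoform IDs. As CPM are not counts, limma was the main test. edgeR 4.0.16 (quasi-likelihood test with TMM) and DESeq2 1.42.0 were run on the recovered reads as alternatives, and edgeR called 5, 88, 3 and 1366 genes in D against CK and in DB, DSi and DBSi against D.

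Named genes followed a rule fixed before the data were examined. Among genes past the threshold whose groups did not overlap and whose mean was 10 CPM or more in the higher group, the 2 largest rises and 2 largest falls in each comparison were named, and for isoforms at most 2 in each direction. The same rule was applied to the 3 comparisons with CK added afterwards. For the interaction the condition on overlap was not applied, and all 23 positive and 7 negative called genes were eligible. For ratios, a group with all libraries at 0 was set to a floor of 3 reads per library. Means of groups with 1 to 3 reads in total carry a counting interval.

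The tests were tried on simulated counts drawn at the real mean of each gene or isoform, with the real library sizes. Their spread was estimated within all 5 groups. Changes were placed in D, in genes or isoforms with a mean of 10 CPM or more, so recovery below that mean was not measured. Of 100 genes changed 4-fold among 22654, limma recovered 87%, edgeR 84% and DESeq2 91%, and of 100 changed 2-fold 21%, 20% and 36%. The false share of calls was 2.7%, 0.952% and 15.3%. For 35504 isoforms limma recovered 65% of 4-fold and 7% of 2-fold changes, with 7.69% of calls false. The F-test over 5 groups recovered 50% of 200 changed genes with 5.66% of calls false. With counting noise alone, diffSplice recovered 96.9% of 4-fold and 58.6% of 2-fold changes with 12.8% of calls false. Values for the move back of drought genes with no added effect came from 100 simulations in which only the 11 called genes differed between CK and D. That setting replaced an earlier version, in which every gene kept its observed CK and D means. It called 670 genes on average against 11 in the data, and gave shares of 69.5%, 69.4% and 69.6%. Genes were drawn independently, so the spread of simulated values is too narrow where libraries share deviations.

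Alternatives were another pseudocount (0.5 or 2), no filter or a filter at 5 CPM, median-of-ratios and quantile scaling, limma without trend or with library weights, only the compared groups in the fit, a minimum log2 difference of 1, a replicate block, edgeR, DESeq2 and each library left out. Alternatives chosen after the data were seen were thinning of every library to 3039422 reads, leaving out isoforms that dropped to 0 within a group, joining loci to reference genes by equal reads in all 15 libraries, counting estimates of exactly 0 with the opposite signs for the move back, choosing the genes of DBSi against D with 2 D libraries and measuring them from the third, and regrouping the residuals of the additive model for the interaction. Figures were drawn with matplotlib 3.10.9.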

Results

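Full-length cDNA of whole 45-day-old seedlings of Glycyrrhiza uralensis, the licorice plant, a legume of dry regions, was sequenced on a nanopore instrument, which reads each cDNA molecule from end to end. The 15 libraries fell into 5 groups of 3. Well-watered plants (CK) were kept at 65 to 75% of the moisture of saturated sand, and droughted plants (D) at 35 to 45%. Droughted plants also received the bacterium Bacillus pumilus strain G5 (DB), silicon at 2 mM (DSi), or both (DBSi). The labels give no moisture or silicon dose for DBSi. Libraries are named by group and replicate, so that D-1 is replicate 1 of D. They held between 3039422 and 4043823 reads assigned to genes, and from 23011 genes (DB-3) to 25321 genes (DSi-3) had at least 1 read. A single read was worth 0.247 to 0.329 CPM, the share of a library's reads scaled to a fixed total. The mean number of reads per library was 3353000 ± 144000 (SD, n = 3) in DBSi and 3273000 ± 225000 (SD, n = 3) in D.

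Libraries of a group resembled each other slightly more than libraries of different groups. The mean Spearman correlation across genes was 0.933 over the 15 pairs within groups and 0.918 over the 90 pairs between groups (permutation test with 1e+05 resamples, one-sided p = 0.00061). In a check for a library deposited more than once, where sampling of the same reads would give a chi-square per degree of freedom near 1, the lowest value was 5.37. It belonged to DB-2 and DSi-2, a pair from different groups that also had the highest correlation (0.959), and the lowest within a group was 8.07. In the plot of principal components, the 3 DBSi libraries had first-component scores of 24.49, 74.84 and 65.41. DB-3 (46.75) and D-2 (20.53) also lay on that side, and the scores of the other CK, D, DB and DSi libraries ran from -60.56 to 8.47. DB-3, D-2 and CK-3 had second-component scores of -75.21, -47.32 and -45.39, apart from their own groups. The groups differed at 987 of 22654 genes by limma's moderated F-test, and 617 of these (62.5%) had their highest mean in DBSi. Of all tested genes, 21.2% had their highest mean in DBSi and 28.3% in CK. The count was 607, 566 and 568 without DBSi-1, DBSi-2 and DBSi-3, and 2181 in DESeq2.

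**Figure D1:**
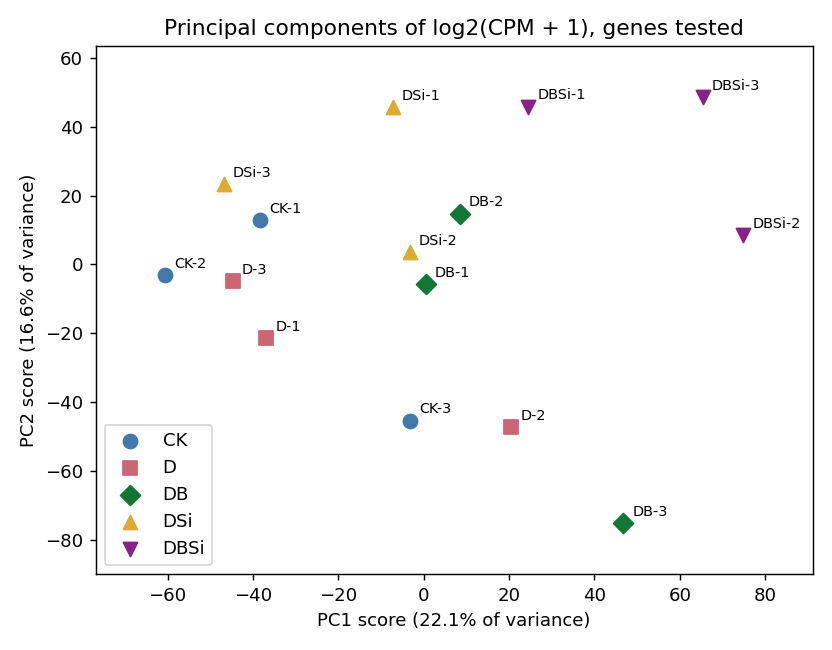
Scores of the 15 libraries on the first principal component (22.1% of variance, horizontal axis) and the second (16.6%, vertical axis) of log2(CPM + 1), with colour and symbol for the group. DBSi libraries lie at 24.49 to 74.84 on the first component, and DB-3, D-2 and CK-3 lie lowest on the second.

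The first question was which transcripts droughted seedlings gained or lost relative to watered ones. In D, 11 genes were lower than in CK and 0 were higher. Glyur001233s00029980 fell from 66.9 ± 68 CPM (SD, n = 3) in CK to 0.813 ± 0.87 CPM (SD, n = 3) in D, 82.3-fold lower. Its CK libraries ran from 22.4 to 145 CPM, and all 3 D libraries lay at 1.82 CPM or less, from 8 reads in total. Glyur000025s00003312 fell from 94 ± 83 CPM (SD, n = 3) to 1.48 ± 0.99 CPM (SD, n = 3), 63.3-fold lower. Their log2 differences were -4.85 (SE 0.62, limma adjusted p = 0.0089) and -4.73 (SE 0.67, limma adjusted p = 0.0158). The median absolute log2 difference of the 11 genes was 3.31. At an unadjusted p under 0.05, limma listed 1806 genes. edgeR's quasi-likelihood test called 5 genes, all lower, and DESeq2 called 98, of which 8 were higher. With the CK and D libraries alone in the fit, limma called 0 genes, and with a filter at 5 CPM 4. The count was 3 without CK-2, 20 without CK-3, 4 without D-1 and 3 without D-2. Glyur001233s00029980 lost its call without D-1 or D-2, and Glyur000025s00003312 without CK-2 or any of the 3 D libraries.

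The next question was whether the genes lowered by drought moved back with an added treatment. Of the 11 genes, 90.9% were higher in DB than in D, 90.9% in DSi and 72.7% in DBSi. Glyur000001s00000113, at 0 CPM in both D and DBSi, is not counted as higher, a rule changed after the first result was seen. Counting such ties gave 81.8% in DBSi and 58.8% in the simulations described next. D libraries enter both comparisons. Simulated libraries with no effect of the added treatment gave 52.4% (95% of simulations 30 to 75%), 51.5% (22.2 to 82.6%) and 50.4% (26.7 to 79.9%). They took the observed means of the 11 genes as true, so they hold little of the shift from choosing genes low in D by chance. The earlier setting, which kept every gene's observed means and called 670 genes, gave 69.5%, 69.4% and 69.6%. Neither setting fixes the share expected with no effect. When 2 D libraries chose the genes and the third was the baseline, the shares over 16 choices were 81.2%, 68.8% and 62.5%. The DBSi share was 33.3% of 3 genes without D-2, 50% without D-1 (4 genes) or DBSi-3 (10 genes) and 100% of 3 genes without CK-2. Relative to D, the median log2 value of the 11 genes was 3.31 higher in CK, and 0.81, 0.73 and 0.78 higher in DB, DSi and DBSi. Means were below that of CK for 10, 11 and 11 of the 11 genes, which were chosen for being higher in the same CK libraries. Glyur001233s00029980 stood at 6.49 ± 1.9, 11.2 ± 4.5 and 2.74 ± 2.5 CPM (SD, n = 3) in those groups. Of the 11 genes, 1 was called higher in DB than in D, 0 in DSi and 2 in DBSi. Relative to CK, 6 were called lower in DB, 5 in DSi and 9 in DBSi, where independent lists would share 0.0068, 0.00583 and 0.29 genes. Simulated unchanged groups that shared the CK libraries had 0.02, 0.01 and 0.02 calls in common. No gene differed in those simulations, so they cannot measure the overlap that shared libraries give. Part of the excess may come from the shared CK libraries.

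Adding G5 to droughted plants changed 111 genes relative to D, 81 of them higher and 30 lower. Glyur000077s00006684 rose 15.9-fold, from 3.41 ± 3.8 to 54.1 ± 18 CPM (SD, n = 3), and Glyur000605s00024928 rose 9.57-fold, from 22.5 ± 12 to 216 ± 83 CPM (SD, n = 3). Glyur001931s00037071 fell from 23.5 ± 7.3 to 2.84 ± 2.6 CPM (SD, n = 3), 8.3-fold lower. The abundant Glyur000008s00001267 fell from 773 ± 210 to 151 ± 10 CPM (SD, n = 3), 5.12-fold lower, and stood at 951 ± 450 CPM in CK. Log2 differences of the 4 genes were 3.98 (SE 0.6, limma adjusted p = 0.0115), 3.25 (SE 0.56, limma adjusted p = 0.0219), -3 (SE 0.52, limma adjusted p = 0.0219) and -2.31 (SE 0.27, limma adjusted p = 0.00258). The count of 111 depended on single libraries. It was 24, 61 and 58 without D-1, D-2 and D-3, 33, 50 and 25 without DB-1, DB-2 and DB-3, 68 without DSi-2 and 69 without DBSi-2. With the DB and D libraries alone it was 45, without limma's trend 51, with a replicate block 71, with library weights 230 and in DESeq2 456. Without each of several D and DB libraries, Glyur000077s00006684 (D-1, DB-3), Glyur000605s00024928 (D-1, D-2 and any DB library) and Glyur001931s00037071 (any D library, DB-1) lost their calls.

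Silicon under drought changed 6 genes relative to D, 4 higher and 2 lower. Glyur000231s00022077 rose 3.92-fold, from 29.4 ± 3.2 to 115 ± 21 CPM (SD, n = 3; log2 difference 1.92, SE 0.25, limma adjusted p = 0.0252), and Glyur001793s00029326 rose 3.47-fold, from 116 ± 16 to 404 ± 140 CPM (SD, n = 3; limma adjusted p = 0.0472). Glyur000694s00023245 fell 4.34-fold, from 44.4 ± 15 to 10.2 ± 4.3 CPM (SD, n = 3; limma adjusted p = 0.0472). Glyur000008s00001267, which also fell in DB, fell 3.52-fold to 220 ± 26 CPM (SD, n = 3; limma adjusted p = 0.0472). The count fell to 0 without D-1, D-2, DB-1 or any of the 3 DSi libraries, and was 15, 11 and 12 without CK-1, CK-2 and DBSi-3, 3 without CK-3, DB-2 or DB-3, and 2 without D-3 or DBSi-1. limma listed 1803 genes at an unadjusted p under 0.05, edgeR called 3, all higher, and DESeq2 162. limma called 0 genes without its trend or with a replicate block, 3 with no filter or with thinned libraries (chosen after the data were seen) and 16 with library weights. With the DSi and D libraries alone it called 8, of which 1 was among the 6. Of the 4 rises, 3 were also called in DB against D, and both falls were, where independent lists would share 0.0143 and 0.00265 genes and simulated unchanged groups shared 0.02. No gene differed in those simulations, so they cannot measure the overlap that shared libraries give. With only 3 D libraries, part of such an excess may come from the shared D libraries.

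Both treatments together gave the longest list among the comparisons with D. DBSi differed from D at 1401 genes, 1036 higher and 365 lower, with a median absolute log2 difference of 1.44. Glyur000010s00000926 rose 64.8-fold, from 2.56 ± 1.3 CPM in D to 166 ± 42 CPM in DBSi (SD, n = 3), and stood at 10.1 ± 1.5 in DB and 26.6 ± 30 in DSi. Glyur000036s00004638 rose 36-fold, from 5.01 ± 1.5 to 180 ± 40 CPM (SD, n = 3). Glyur000690s00025177 fell 29.4-fold, from 37.1 ± 6 to 1.26 ± 1.1 CPM (SD, n = 3), and Glyur000056s00004163 fell 18.8-fold, from 103 ± 75 to 5.48 ± 5.4 CPM (SD, n = 3). Log2 differences of the 4 genes were 5.58 (SE 0.58, limma adjusted p = 0.000104), 4.92 (SE 0.46, limma adjusted p = 5.5e-05), -4.17 (SE 0.51, limma adjusted p = 0.000243) and -4 (SE 0.92, limma adjusted p = 0.018). Glyur000056s00004163 lost its call without D-1, DBSi-2 or DBSi-3. Across the 15 leave-one-out fits the count was lowest at 727 without DBSi-3, 786 without D-1 and 861 without D-3. Among genes called in DB against D, 68 of 81 higher and 24 of 30 lower kept their call and direction in DBSi against D. Independent lists would share 3.7 and 0.483, and simulated unchanged groups shared 0.04. No gene differed in those simulations, so they cannot show how much overlap the shared D libraries give lists of this length. Part of the excess may come from those libraries. The covariance of the DB and DBSi log2 differences from D was 0.207 across genes, against 0.09 in simulated unchanged groups. It was 0.114 (0.047 to 0.148 over 3 choices) when the comparisons used different D libraries. The simulated 0.09 comes from sharing the D libraries, so it is not the reference for that value. Genes are not independent replicates, so no test is attached to it.

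**Figure D2:**
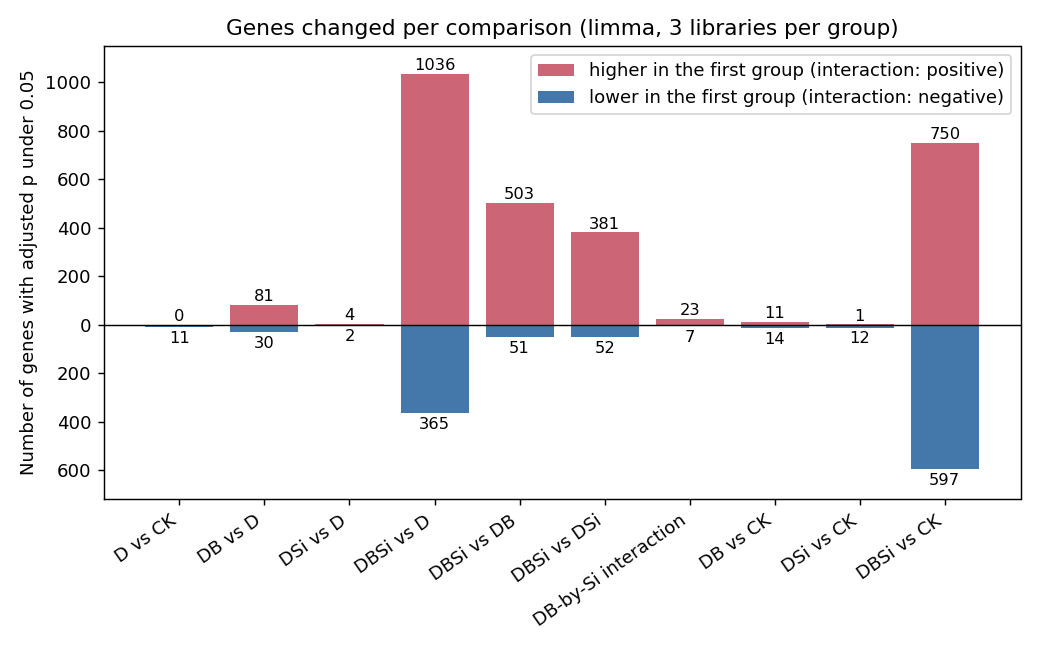
Number of genes with a limma adjusted p under 0.05 (vertical axis) in each comparison, upward for genes higher in the first-named group and downward for genes lower, and for the interaction upward and downward for its sign. The bars for DBSi against D reach 1036 and 365, and those for D against CK 0 and 11.

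Against each single treatment, DBSi differed at 554 genes from DB (503 higher) and at 433 genes from DSi (381 higher). Glyur000036s00004638 stood at 4.36 ± 0.98 CPM in DB, 14.6 ± 13 in DSi and 180 ± 40 in DBSi (SD, n = 3), 41.3-fold and 12.4-fold higher in DBSi (limma adjusted p = 0.000197 and 0.00104). Glyur000340s00024368 was 42-fold higher in DBSi than in DB, at 133 ± 50 against 3.16 ± 0.99 CPM (SD, n = 3; limma adjusted p = 0.00179). Glyur000190s00015737 lay between 5.95 and 7.7 CPM in the means of the other 4 groups and at 71.5 ± 19 CPM in DBSi (SD, n = 3), 12-fold higher than in DSi (limma adjusted p = 0.000145). Lower in DBSi than in DB were Glyur000751s00027025 (12 ± 6 against 109 ± 88 CPM, SD, n = 3; limma adjusted p = 0.0458) and Glyur000690s00025177 (limma adjusted p = 0.016). Lower in DBSi than in DSi were Glyur002055s00039240 (2.04 ± 2.1 against 80 ± 51 CPM, SD, n = 3; limma adjusted p = 0.0322) and Glyur000080s00008697 (0.828 ± 1.4 against 27 ± 13 CPM, SD, n = 3; limma adjusted p = 0.0357). The DB count was 316, 362 and 363 without DB-3, DBSi-1 and DBSi-3. The DSi count was 172, 154, 264, 226 and 245 without DSi-2, DSi-3, DBSi-1, DBSi-2 and DBSi-3, 281 with these 2 groups alone, and 810 in DESeq2. The 4 falls named here each lost their call without at least 1 library.

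**Figure D3:**
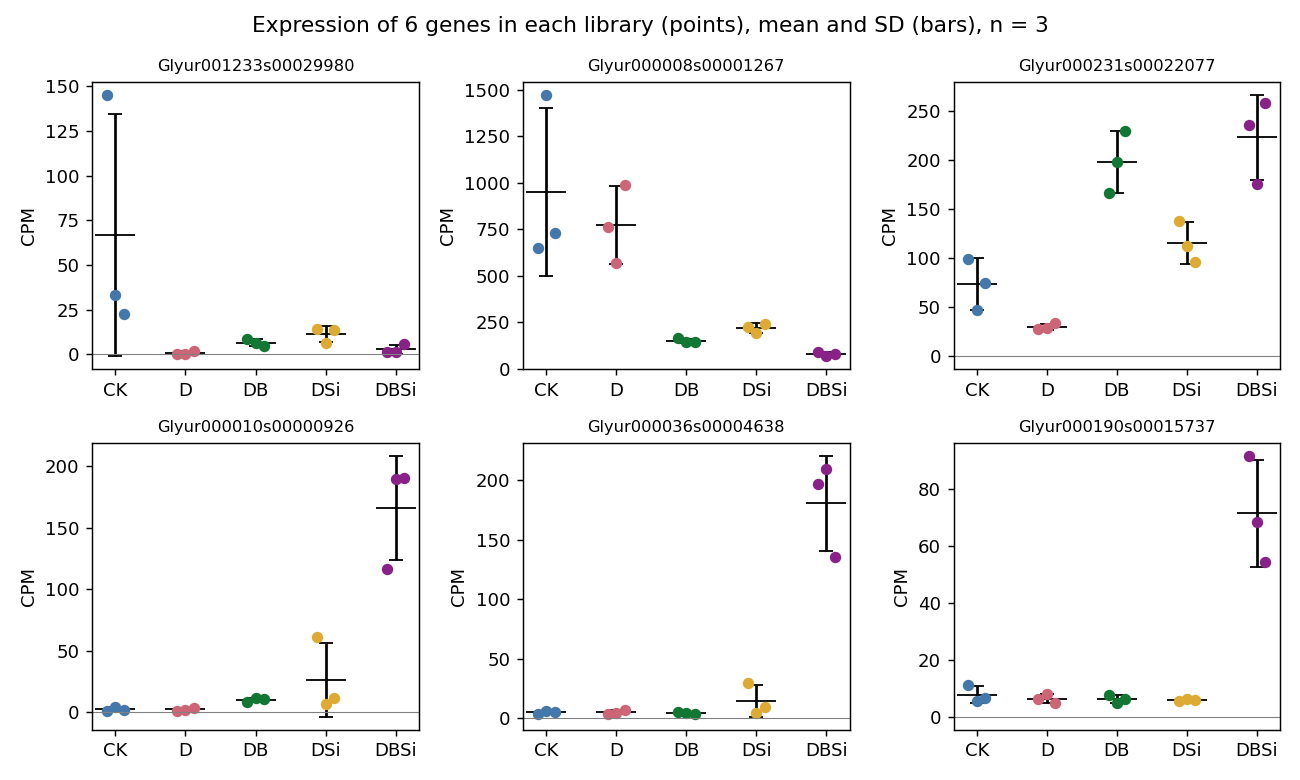
CPM of 6 genes (vertical axes) in the 3 libraries of each group (points), with the mean and SD (black bars). Glyur000036s00004638 lies at 135 to 209 CPM in DBSi and at 29.6 CPM or less elsewhere, and Glyur000008s00001267 at 68.7 to 242 CPM in DB, DSi and DBSi and 567 CPM or more in CK and D.

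Whether silicon acted differently with and without G5 was tested as an interaction over the 4 droughted groups. The test takes the moisture of DBSi as in the other droughted groups and its silicon dose as in DSi, which the labels do not give. limma called 30 genes, 23 of them positive, meaning more expression under both treatments than the sum of the separate log2 differences. The 2 leading positive genes were Glyur006359s00047467 (interaction 4.83, SE 0.8, limma adjusted p = 0.039) and Glyur000036s00004638 (4.02, SE 0.64, limma adjusted p = 0.039). The first stood at 7.88 ± 3.6 CPM in D, 0.918 ± 1.3 in DB, 8.34 ± 5.8 in DSi and 48.6 ± 24 in DBSi (SD, n = 3). The 2 leading negative genes were Glyur000624s00026886 (-2.14, SE 0.36, limma adjusted p = 0.0397) and Glyur001793s00029326 (-2.09, SE 0.37, limma adjusted p = 0.0499). The first of these stood at 15.5 ± 1.1 CPM in D, 33.5 ± 9.9 in DB, 26.1 ± 4.5 in DSi and 11.6 ± 3.1 in DBSi (SD, n = 3). The count was 2 without D-1, D-2, DSi-2, DSi-3, DBSi-1 or DBSi-2, 5 to 11 without D-3 or any DB library, 18 without CK-1 and 144 without DSi-1. It was 3 without limma's trend, 17 with a pseudocount of 0.5 or in edgeR, 19 with no filter or with a replicate block, 75 with library weights and 277 in DESeq2.

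Comparisons of the treated droughted plants with watered plants were added after the data were seen. DB differed from CK at 25 genes (11 higher), DSi at 13 (1 higher) and DBSi at 1347 (750 higher). Glyur000049s00003169 was 3.96-fold higher in DB than in CK, at 180 ± 19 against 45.3 ± 21 CPM (SD, n = 3; limma adjusted p = 0.0477), and Glyur005525s00046106 4.19-fold, at 57.8 ± 28 against 13.8 ± 3.2 CPM (SD, n = 3; limma adjusted p = 0.0255). Glyur000816s00024880 was 3.24-fold higher in DSi, at 19.4 ± 0.55 against 5.99 ± 0.76 CPM (SD, n = 3; limma adjusted p = 0.0121). Glyur000910s00020573 was lower in DB, at 0.202 ± 0.17 against 10.6 ± 2.3 CPM (SD, n = 3), a ratio of 52.7 with a counting interval from 14 to 434 (limma adjusted p = 0.00156), and Glyur000025s00003312 27.9-fold lower (limma adjusted p = 0.0466). Lower in DSi were ONT.4231, 17.9-fold at 1.51 ± 1.2 against 27 ± 15 CPM (SD, n = 3; limma adjusted p = 0.0498), and Glyur000228s00011929, 15.4-fold at 1.8 ± 0.34 against 27.7 ± 15 CPM (SD, n = 3; limma adjusted p = 0.0132). In DBSi, Glyur000010s00000926 was 65.8-fold and Glyur000036s00004638 37.3-fold higher (limma adjusted p = 9.85e-05 and 6.07e-05). Glyur001117s00026958 was lower in DBSi, at 0.204 ± 0.18 against 85.3 ± 18 CPM (SD, n = 3), a ratio of 419 with a counting interval from 119 to 3580 (limma adjusted p = 0.00228), and Glyur002055s00039240 83.3-fold lower (limma adjusted p = 0.00533). The calls of Glyur000816s00024880 and Glyur000228s00011929 were lost without CK-2 or any DSi library, that of Glyur005525s00046106 without any CK library, DB-1 or DB-3, and those of ONT.4231, Glyur000049s00003169 and Glyur000025s00003312 without most of the libraries. With median-of-ratios scaling 69.6% of the DBSi calls were higher, against 55.7% as deposited, 62.9% with quantile normalization and 69% in edgeR. The corresponding shares for DB were 58.6%, 44%, 59.3% and 57.7%, and for DSi 22.2%, 7.69%, 18.2% and 16.7%. With only the compared groups in the fit, limma called 0, 0 and 778 genes. DB gave 11 genes without the trend and 227 in DESeq2, and DSi 8 with a pseudocount of 0.5 or a replicate block, 5 with a filter at 5 CPM, 6 in edgeR and 122 in DESeq2. The DBSi count was 776, 845 and 722 without CK-2, DBSi-2 and DBSi-3, the DB count 3, 13 and 8 without CK-2, DB-2 and DB-3, and the DSi count 22 without CK-1, 2 without CK-2 or DSi-3, 1 without DSi-1 or DSi-2, and 7 or 8 without CK-3, DB-1, DBSi-2 or DBSi-3. Over all genes tested the median log2 difference from CK was -0.138 in DB, -0.004 in DSi and -0.115 in DBSi, a shift that was not subtracted from the changes given.

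In D against CK, 16 isoforms changed (2 higher), in DB against D 77 (57 higher), in DSi against D 2 (1 higher) and in DBSi against D 1668 (1273 higher) of 35504 tested. ONT.14848.5 was listed at 0 in every CK library and at 37 ± 3.7 CPM in D (SD, n = 3), at least 41.2-fold higher against a floor of 3 reads per library (limma adjusted p = 2.06e-08). ONT.20285.4 was at 0 in every CK and DBSi library and at 55.3 ± 21 CPM in D (SD, n = 3; limma adjusted p = 0.026 against CK and 0.00144 for DBSi). Lower in D than in CK were Glyur001233s00029980.1 (61.9 ± 60 to 0.813 ± 0.87 CPM, SD, n = 3; limma adjusted p = 0.0137) and Glyur000025s00003312.1 (94 ± 83 to 1.48 ± 0.99 CPM, SD, n = 3; limma adjusted p = 0.0281). ONT.13827.3 was at 0 in every D library and at 33.1 ± 22 CPM in DB (SD, n = 3; limma adjusted p = 0.0224). ONT.1041.1 was higher than in D (1.22 ± 2.1 CPM) in both DB (42.3 ± 11) and DSi (47.2 ± 22 CPM, SD, n = 3; limma adjusted p = 0.00326 and 0.00787), and stood at 37 ± 9.7 CPM in CK. ONT.1841.1 was at 0 in every DB library and at 40.2 ± 24 CPM in D (SD, n = 3; limma adjusted p = 0.000589), as was ONT.2559.2, at 21.4 ± 8.9 CPM in D (SD, n = 3; limma adjusted p = 0.000265). ONT.587.1 was lower in DSi, at 1.73 ± 1.1 against 25.2 ± 2.1 CPM (SD, n = 3; limma adjusted p = 0.00787). At 0 in every D library and higher in DBSi were ONT.16362.3 (102 ± 88 CPM, SD, n = 3; limma adjusted p = 0.0277) and ONT.15465.10 (64.2 ± 21 CPM, SD, n = 3; limma adjusted p = 0.000179), and ONT.7818.2 was at 0 in every DBSi library and at 31.7 ± 7 CPM in D (SD, n = 3; limma adjusted p = 1.03e-05). In the file, 14% of isoforms with at least 20 reads in a library stood at 0 in another library of the same group, against 3.04% of genes, which bears on every isoform listed at 0. The calls of ONT.16362.3 (any D or DBSi library), ONT.13827.3 (any D library, DB-2, DB-3), ONT.20285.4 against CK (any CK or D library, DBSi-3), Glyur001233s00029980.1 (CK-2, D-1, D-2) and Glyur000025s00003312.1 (CK-2, CK-3, any D library, DSi-3, DBSi-3) were lost without the libraries given. The DBSi count was 931, 1070, 1090 and 832 without D-1, D-3, DBSi-2 and DBSi-3. The DB count was 29, 25 and 46 without D-1, D-2 and D-3, 43, 16 and 13 without DB-1, DB-2 and DB-3, and 51 without DSi-2. The D count was 5 and 8 without CK-2 and D-2, and the DSi count 5 without CK-1 or DBSi-2, 7 without D-1 or D-3, and 10 without DSi-3. With a filter at 5 CPM the D count was 8. The DSi count was 8 with no filter and 4 with median-of-ratios scaling. Without isoforms that dropped to 0 within a group, an alternative chosen after the data were seen, the DB count was 118 and the DSi count 7.

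Isoform use within a locus, tested with limma's diffSplice at 5138 loci with 2 or more isoforms, passed the threshold at 14 loci in D against CK, 19 in DB against D, 9 in DSi against D and 59 in DBSi against D. Without isoforms that dropped to 0 within a group, the counts were 5, 3, 2 and 65. At an unadjusted p under 0.05 there were 374, 473, 413 and 713 loci. Data were simulated for D against CK with the spread of the real libraries. A single isoform per changed locus, with a mean of 10 CPM or more, was altered. Of these changes, 23% of 4-fold and 1.72% of 2-fold were recovered, and 23.3% of the calls were false. The DBSi count was 38, 35 and 35 without D-2, DBSi-2 and DBSi-3, the DB count 34 and 29 without DB-1 and DSi-1, and the DSi count 14 to 23 without CK-3, DSi-1, DSi-3 or any D library. The DSi count was also 14 with a pseudocount of 0.5 or a replicate block, and the DBSi count 108 with loci joined to reference genes, an alternative chosen after the data were seen.

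**Figure D4:**
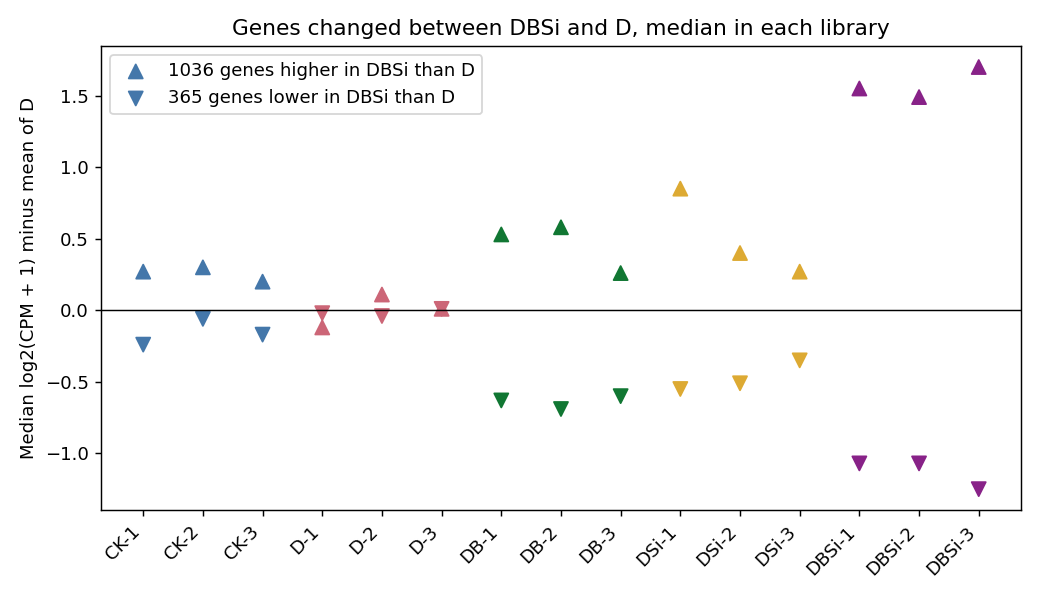
Median difference in log2(CPM + 1) from the mean of D (vertical axis) in each library (horizontal axis), over the 1036 genes higher in DBSi than in D (upward triangles) and the 365 lower (downward triangles). DBSi libraries, on which the genes were chosen, lie at 1.49 to 1.7 and at -1.25 to -1.07, and the highest of the other libraries is DSi-1 at 0.85.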

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

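The interaction term was planned before the data were examined. The regroupings of residuals and the thinning were added after the data were seen. The interaction term called 30 genes whose response to silicon differed with and without G5. Of the 23 positive genes, 20 were also called higher in DBSi than in D, 3 were called in DB against D and 0 in DSi against D by limma, where edgeR called 3 and DESeq2 162 genes in all and limma listed 1803 at an unadjusted p under 0.05. In 23 of these 23 genes every DBSi library lay above every DB and DSi library, which the choice of genes favours. Of the 7 negative genes, 4 were called in DB and 3 in DSi against D. With 100 regroupings of the 12 droughted libraries, the real one included, 3 gave 30 or more genes. These regroupings mix groups that differ at many genes, so they exclude nothing for an interaction, and the highest other gave 184 genes. Regrouping the residuals of the additive model instead keeps the separate differences of G5 and silicon. Of 100 such regroupings, the real one included, 3 gave 30 or more genes, a share under 0.05. Another regrouping reached 35 genes, so chance is less likely by this count but not excluded. The highest other gave 254 genes, several times the real count, which points to a structure of the samples. It put the residuals of D-2, DB-3, DSi-1, DSi-2, DBSi-2 and DBSi-3 against those of the other 6 libraries, and the source of that structure stays open. The count was 144 without DSi-1, 18 without CK-1, 10 without D-3, 6, 5 and 11 without DB-1, DB-2 and DB-3, and 2 without D-1, D-2, DSi-2, DSi-3, DBSi-1 or DBSi-2. It was 3 without limma's trend, 17 with a pseudocount of 0.5 or in edgeR, 19 with no filter or with a replicate block, 75 with library weights and 277 in DESeq2. With every library thinned to the lowest total it was 32 (27 of the 30 genes among them), with median-of-ratios scaling 31 (26 of the 30) and with quantile normalization 33 (26 of the 30). No source other than chance, depth and scaling was examined. As the labels give no moisture or silicon dose for DBSi, a difference in either cannot be told apart from an interaction.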

How the results depend on the processing

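Tests on thinned libraries, on isoforms left out for dropping to 0, on joined loci, and all values for comparisons with CK other than D against CK were chosen after the data were seen. DBSi against D and DBSi against DB kept their counts within 1.5 times under every alternative other than leaving out a library. The isoform count of DBSi against D did so with a pseudocount of 0.5, no filter, a filter at 5 CPM, median-of-ratios scaling, a replicate block and isoforms that dropped to 0 left out, and the other alternatives were not run for isoforms. Counts that moved further are given here. The cause was not tested unless stated. With a pseudocount of 0.5 the interaction called 17 genes, DSi against CK 8, and isoform use in DSi against D 14 loci. With no filter, DSi against D called 3 genes and 8 isoforms, and the interaction 19 genes. With a filter at 5 CPM, which tests fewer genes, D against CK called 4 genes and 8 isoforms, and DSi against CK 5 genes. Without the trend, DB against D called 51, DSi against D 0, the interaction 3 and DB against CK 11 genes. With library weights, DB against D called 230, DSi against D 16 and the interaction 75 genes. With only the groups compared, which leaves fewer libraries to estimate the spread, the counts were 0 for D against CK, 45 for DB against D, 281 for DBSi against DSi, 0 for DB against CK, 0 for DSi against CK and 778 for DBSi against CK. edgeR called 5 genes in D against CK, 3 in DSi against D, 17 for the interaction and 6 in DSi against CK. DESeq2, which gave 15.3% false calls in the simulation of D against CK, called 98 in D against CK, 456 in DB against D, 162 in DSi against D, 810 in DBSi against DSi, 277 for the interaction, 227 in DB against CK, 122 in DSi against CK and 2181 over the 5 groups. Thinning gave 3 genes in DSi against D, and median-of-ratios scaling 4 isoforms. Without the isoforms that dropped to 0, DB against D called 118 isoforms and DSi against D 7, and isoform use passed the threshold at 5, 3 and 2 loci in D against CK, DB against D and DSi against D. Joining loci to reference genes gave 108 loci in DBSi against D.

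On average, libraries with the same replicate number did not deviate together. Over 30 pairs with the same number in different groups, the correlation of deviations from the group means ran from -0.22 to 0.33. Its mean was 0.01, against 0 over the other pairs, whose highest value was 0.29. The correlation was over 0.1 in 8 of the 30 pairs and highest for D-2 and DBSi-2. Of 15 libraries, 6 correlated best with a library of their own number. A batch shared by only some groups is not excluded by these values. With the replicate number as a block, DB against D called 71 genes, DSi against D 0, the interaction 19 and DSi against CK 8, and isoform use in DSi against D changed at 14 loci.

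Leaving out each library in turn gave 3 to 20 genes in D against CK, 24 to 154 in DB against D, 0 to 15 in DSi against D, 727 to 1459 in DBSi against D, 316 to 575 in DBSi against DB, 154 to 566 in DBSi against DSi, 2 to 144 for the interaction and 566 to 970 over the 5 groups. For DB, DSi and DBSi against CK it gave 3 to 28, 1 to 22 and 722 to 1456 genes. Isoform counts were 5 to 19, 13 to 103, 2 to 10 and 832 to 1711 in D against CK and in DB, DSi and DBSi against D. Isoform use changed at 13 to 20, 13 to 34, 9 to 23 and 35 to 83 loci. Shares of drought genes with the opposite sign were 66.7 to 100% in DB, 61.5 to 100% in DSi and 33.3 to 100% in DBSi. Where a fit left a group with 2 libraries, all groups shared the estimate of spread. None of 51 named results changed direction in 1359 alternative values. Outside the interaction, the naming rule took only groups that did not overlap, so leaving out a library could not reverse their sign. Nor could another pseudocount or filter, the fit without trend, library weights, the replicate block, only the compared groups or a minimum difference. Scaling, thinning, edgeR and DESeq2 could have, but the features named had the largest differences. In 291 of the 1359 values the call was lost, 208 of them on leaving out a library. Camera with an estimated correlation, quantile normalization and a replicate block for gene lists were not run, since no names were at hand. The simulation of D against CK had the depth and spread of these libraries. There, 21% of 2-fold changes were recovered in genes with a mean of 10 CPM or more. How much of that is due to depth was not tested for genes. For isoform use, at the same depth and cut, 1.72% of 2-fold changes were recovered with the spread of the data and 58.6% with counting noise alone.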

Other observations

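The tests of sibling isoforms, of median-of-ratios scaling and of low counts, and the count of isoforms at 0 in a whole group, were chosen after their results had been seen, at least in part. The thinning, the comparisons with CK and the baseline of a single D library were also chosen after the data were seen.

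Over the 1036 genes higher in DBSi than in D, the median log2 difference from D was 0.44 in DB, 0.5 in DSi and 1.58 in DBSi, and 864 and 958 of them had a higher mean in DB and DSi than in D. Over the 365 lower genes it was -0.65, -0.47 and -1.16. In CK, which had neither treatment, the median difference from D was 0.25 over the higher genes and -0.2 over the lower ones. The D libraries enter the choice of these genes and the differences, which alone shifts the values this way. When 2 D libraries chose the genes and the third was the baseline, the medians over the higher genes were 0.56, 0.22 and 0.39 in DB and 0.65, 0.25 and 0.47 in DSi with D-1, D-2 and D-3 as the baseline. Over the lower genes they were -0.48, -0.31 and -0.52 in DB and -0.33, -0.04 and -0.42 in DSi. A shift of that baseline library across all genes was not subtracted. Within DSi, DSi-1 stood apart, with a median of 0.85 over the higher genes against 0.4 in DSi-2 and 0.27 in DSi-3. Glyur000010s00000926 was at 61.3 CPM in DSi-1 and at 7.2 and 11.4 CPM in the other DSi libraries, and Glyur000036s00004638 at 29.6, 4.5 and 9.64 CPM.

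DBSi against D called 1401 genes, against 111 and 6 for DB and DSi. Removal of the 2 main axes of deviation within groups left 92.8% of the mean absolute log2 difference of these 1401 genes. The value was 91.3 to 96% with each library left out. Deviations on those axes therefore account for little of the size of these differences. Calls were not counted again after the removal, so whether deviations shared across groups raised the number of calls was not tested. In the simulation of D against CK, removal of a single axis kept 99.8% of known changes and left 16.6% of an added axis with random loadings. Removal of 2 axes was not tried there, and removal of a single axis here left 101%. A deviation common to all DBSi libraries is not a deviation within groups, so this method cannot remove it. Depth is argued against as a source of the longer list, with 1340 calls after every library was thinned to the lowest total. So is scaling by total reads, since the ratio of DBSi to DB calls was 13.3 with median-of-ratios scaling. What stays open is the combined treatment itself and any difference in sowing, harvest or library preparation, since the labels give no batch. Also open is a moisture or silicon dose of DBSi unlike that of the other groups, since the labels give neither. For the number of calls, deviations shared across groups stay open too.

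Of these genes 73.9% were higher in DBSi. Scaling does not account for that share, which was 77.1% with median-of-ratios scaling and 69.9% with quantile normalization. Nor do low counts, as it was 72.3% among called genes with a mean of 10 CPM or more. A response to the combined treatment remains a hypothesis, as do the differences in handling, moisture or silicon dose named above.

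At the isoform level, 3623 isoforms stood at 0 in a library while a replicate had 20 or more reads, in 8963 events. At the gene level there were 952 such events. Poisson sampling of reads at the group mean would give 1.51 isoform events. That value leaves out the spread between libraries beyond counting noise, whose part in the isoform events was not tested. Reads assigned to sibling isoforms of the same locus are a candidate explanation for part of the events. In 81.2% of events the locus, as named by the ID, held another isoform. Of all isoforms with 20 or more reads in a library, 47.5% had such a sibling. The first share counts events and the second isoforms, so they are not fully alike. Locus totals were compared over 2273 events in which the isoform made up 50% or more of its locus. There the median locus total in the library at 0 was 0.877 of that in its replicates, against 0.258 had its reads been lost. The interquartile range was 0.592 to 1.13 and the medians by library 0.734 to 1.07. Treatment as the source was not tested, since an event needs a replicate with reads and so never covers a whole group. A separate count took isoforms at 0 in exactly 3 libraries and with 20 or more reads in each of the other 12. Of these 83 isoforms, 4 were at 0 in the 3 libraries of a group (0.91 expected by chance), which says nothing about the events. True switching between isoforms in single libraries would also keep the locus total and stays open. Isoforms listed at 0 in a whole group may therefore be assignments rather than changes. For ONT.14848.5 the locus total was 38.8 CPM in CK and 36 CPM elsewhere. For ONT.1841.1 and ONT.2559.2 it was 53.3 and 137 CPM in DB, against 58.2 and 182 CPM elsewhere. ONT.2559.2 made up 10.7% of its locus elsewhere. For ONT.7818.2 the locus total was 59.4 CPM in DBSi and 77.4 CPM elsewhere.

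A further hypothesis was that genes with neighbouring IDs change together. Among 20342 reference genes tested, 253 pairs of genes called in the same direction in DBSi against D lay within 10 ID numbers of a shared prefix, against a mean of 191 and a maximum of 246 in 10000 shuffles (permutation p = 1e-04, one-sided, the smallest these shuffles can give). Shuffles within classes of similar mean expression, run after that result was seen, gave a mean of 204 (permutation p = 8e-04, one-sided). The pairs held 385 genes. Whether these are neighbours on a chromosome, or close copies that share reads, was not tested.

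Other splits of the libraries were fitted for each count. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so only values are given. In D against CK the real split gave 11 genes and the highest other 8, in DB against D 111 and 1, in DSi against D 6 and 2, in DBSi against D 1401 and 1, in DBSi against DB 554 and 1, in DBSi against DSi 433 and 0, in DB against CK 25 and 1, in DSi against CK 13 and 2, and in DBSi against CK 1347 and 1. In each of these 1 split, the real one, gave as many. For isoforms the real and highest other counts were 16 and 36 in D against CK (2 splits gave as many), 77 and 7 in DB against D (1 split), 2 and 3 in DSi against D (4 splits) and 1668 and 7 in DBSi against D (1 split). For isoform use they were 14 and 40 (5 splits), 19 and 25 (2 splits), 9 and 13 (6 splits) and 59 and 17 (1 split). For the F-test over 5 groups, 2 of 100 regroupings of the 15 libraries, the real one included, gave 987 or more genes. That share is under 0.05, but the highest other regrouping gave 1135 genes and a further one 560. Chance is less likely by this count but not excluded.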
